A study of Mus musculus with 16 samples.

How the data were processed

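Expression was measured on 16 Affymetrix arrays of biotin-labelled cRNA, prepared from 50 to 100 ng of total RNA of sorted olfactory mucosa cells, per the labels' protocols. The deposited values are log2 signals, 1 table for the whole series, which the authors made with Affymetrix Expression Console, per the submitters' processing notes; its version, the normalization and any background step are not given in the sources used here. The log scale was read from the values. No detection call was used, and the signal of the negative control features served as the measure of background. The table held 28846 features. A platform annotation named 19572 of them with 1 gene symbol and 0 with several, all matched by gene number to a RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes. Of the 9274 features without a gene name, 5222 were negative controls and 1324 positive controls. Where a gene had more than 1 feature (67 further features), the one with the highest mean over all arrays was kept, which left 19505 genes. No filter on dim genes was set, because odorant receptors are each expressed by few cells. No 2 arrays were duplicates: the smallest SD of the log2 differences between any 2 arrays was 0.359.

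Groups and replicate numbers were taken from the sample titles. The cell type field names the sorted fraction the opposite way in all 16 arrays, so the text speaks of arrays titled GFP+ and titled GFP-, and a signed difference is titled GFP+ minus titled GFP-, or odor minus vehicle. Each pool of 3 mice gave both fractions, which the titles tie together by treatment and number. Replicates are separate pools of mice. The labels state that odor and vehicle groups of mice were exposed at the same time but do not say that a shared number marks a shared exposure.

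Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 contrasts between fractions and their difference between treatments were fitted on all 16 arrays with the pool as a fixed block (6 residual degrees of freedom). Odor and vehicle were compared within each fraction by 4 group means with the pool as a random block (estimated correlation 0.164, 12 residual degrees of freedom). The 5 comparisons, their designs, 29 gene lists and the rule for named genes were fixed before the data were examined. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison, for lists with at least 5 measured genes. In the within-fraction comparisons the list tests used data from which the pool correlation had been removed. Lists without a name pattern held 324 genes, of which 285 were measured, and the list of mitochondrially encoded genes had 0 measured members. Camera called 19 lists in each contrast between fractions, and 2 of these calls in each, the neutrophil and the microvillar list, held with an estimated correlation.

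Named genes followed a rule. S100a5 and Omp were named in every comparison. The 10 largest differences in each direction, of genes past the threshold and of 1 sign in all 4 pools, were named between fractions. For the difference between treatments, receptors past the threshold over the receptor list were named, filled up to 10 by smallest p. Within a fraction, the genes past the threshold were named, or the 3 smallest p in each direction where none passed. Up to 4 members with the largest differences, or the members counted where 5 or fewer passed, were named for each list described. The red cell genes Rhag and Epb42 belong to no fixed list and were named outside this rule. Receptors past the list threshold within a fraction, the receptors with the largest positive fraction differences, the genes past the threshold in the paired fits, and Etv5 and Kcng1 were singled out after their values were seen, as were single members of a list, such as Slc24a4, Gng8, Epha5 or Taar9, that stand among examples.

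Pairing was checked on deviations from group means over all genes. The fractions of 1 pool correlated at 0.116 to 0.192 in odor and 0.136 to 0.341 in vehicle pools. Odor and vehicle pools of the same number correlated at 0.198 to 0.279 in the arrays titled GFP-, above 0.1 in 4 of 4 pairs, and each of the 4 odor arrays correlated best with its own number. The numbers were therefore taken to pair the pools, and the fit with the replicate number as a block called 15 genes against 0 without it. In the arrays titled GFP+ of the same pools the correlations were 0.0787 to 0.410, above 0.1 in 3 of 4 pairs, and 3 of the 4 odor arrays correlated best with their own number.

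Alternatives were no block, a random pool block, the replicate number as a block, median centring, cyclic loess, centring on housekeeping genes, omission of genes below the 30th percentile of mean signal, the mean of a gene's features, all features, no variance trend, robust estimation, array weights, receptors fitted alone, and leaving out each pool. Added after the data were seen were centring on mature neuron genes, omission of the pools numbered 4, which lack Y-linked signal, and paired list tests. The procedures were tested on simulated data with 50 changed genes per size among 19505. A log2 change of 1 was recovered for 68% of genes in the vehicle fraction contrast, 78% in the odor one, 34% in the difference between treatments, 80% in odor against vehicle in arrays titled GFP+ and 82% in arrays titled GFP-; a change of 2 was recovered for 98, 100, 96, 100 and 98%. The simulated noise held 1 pool correlation and no structure by replicate number, and genes of every size changed at once. These shares may therefore not hold for the odor comparisons, where few genes passed. There, Olfr937 at -3.07 in the difference between treatments did not pass over all genes (limma, adjusted p = 0.165). A named gene at or below the negative control median of each array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group to that median, or to its own signal where higher in an array, and no size is given where both groups lie there or the bound has the other sign. This rule was added after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.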

Results

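Olfactory mucosa of S100a5-tauGFP mice, a C57BL/6 line that carries a green fluorescent reporter of the S100a5 gene, was profiled on 16 Affymetrix arrays. S100a5 encodes a calcium-binding protein of olfactory sensory neurons whose transcription follows neuronal activity, and the Kentucky assay uses the reporter to sort neurons that responded to an odor in the living animal. The 24 mice, of both sexes and 7 to 12 weeks of age, stayed singly in clean-air chambers for 40 h at an air flow of 3.1 L/min. After the first 26 h they received 10 s pulses every 20 min of filtered air (vehicle) or of whiskey lactone, an aroma compound of oak wood. Cells of 3 mice made up a pool, and each pool was sorted into 2 fractions by fluorescence. The 8 pools, 4 per treatment, gave 4 groups of 4 arrays. The values were log2 signals of 19505 genes, among them 1090 odorant receptors of the Olfr family and 15 trace amine-associated receptors. Median signals of the arrays were 6.08 to 6.47, and those of the negative control features 4.98 to 5.59. Between 58.0 and 66.4% of genes, and between 81.0 and 87.0% of the receptors, exceeded the negative control median of their array. Correlations between arrays were 0.986 to 0.994 within a group, 0.984 to 0.995 between treatments in the same fraction, and 0.927 to 0.968 between fractions. The number of arrays limits the precision of every value.

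S100a5, the gene behind the reporter, was lower in the array titled GFP+ than in the array titled GFP- in all 8 pools. In the odor pools its log2 signal was 15.24 ± 0.30 in arrays titled GFP+ and 16.58 ± 0.13 in arrays titled GFP- (SD, n = 4), a 2.53-fold lower level (log2 difference -1.34 ± 0.09, SE; limma, adjusted p = 2.07e-07). In the vehicle pools the means were 15.28 ± 0.27 and 16.51 ± 0.19 (SD, n = 4), a 2.35-fold lower level (-1.23 ± 0.09, adjusted p = 4.78e-07). Within single pools the difference ran from -1.68 to -0.96. The cell type field of the labels names the sorted fraction the other way round from the title in all 16 arrays. S100a5 was thus higher in the arrays that the cell type field calls GFP+. Groups are named by title throughout, and neither label was changed. If the cell type field is taken instead, each difference between fractions changes sign, and so does its difference between treatments. A difference between odor and vehicle keeps its sign, and only the name of the fraction changes. Omp, the olfactory marker protein of mature sensory neurons, had log2 signals of 18.54 ± 0.07 and 18.68 ± 0.11 in the odor arrays titled GFP+ and GFP- and of 18.59 ± 0.10 and 18.66 ± 0.04 in the vehicle arrays (SD, n = 4). Omp thus lay near the brightest feature of each array (19.09 to 19.24), which limits what its small differences show of neuron content. Its differences of -0.14 ± 0.05 (adjusted p = 0.0667) and -0.06 ± 0.05 (adjusted p = 0.390) did not pass the threshold, and both depended on scaling. They became -0.52 and -0.43 after median centring (adjusted p = 2.71e-05 and 0.000139) and -0.77 and -0.63 after housekeeping centring (3.90e-06 and 2.73e-05). The housekeeping genes lay higher themselves in the arrays titled GFP+ (medians 0.05 and 0.08), so centring on their mean lowers every difference. With arrays centred on the mature neuron genes, of which Omp is itself 1, they became 0.14 and 0.25 (adjusted p = 0.0607 and 0.00208). The medians of those genes were -0.29 and -0.32, lower than Omp, so this turn of sign follows from the centring. Without odor pool 2 the odor difference of -0.18 passed (adjusted p = 0.0384).

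**Figure D1:**
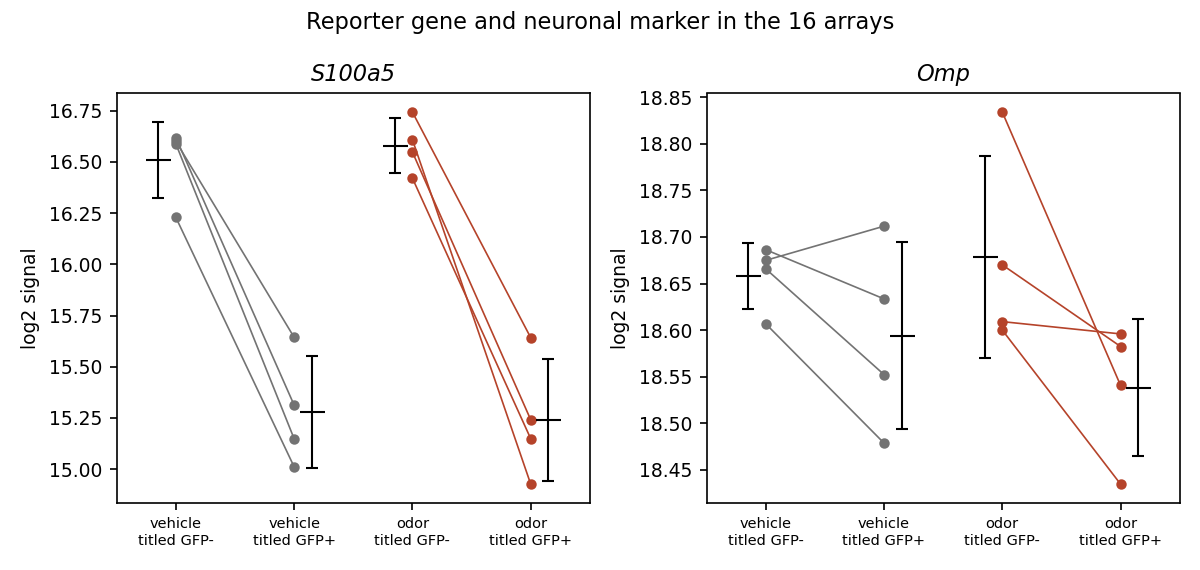
Log2 signal of S100a5 and Omp in each of the 16 arrays (points), with group means and SD (n = 4 pools per group), and lines joining the 2 fractions of a pool; fractions are named by array title, which the cell type field of the labels reverses. S100a5 lies lower in the array titled GFP+ in all 8 pools, with pool differences of -1.68 to -0.96.

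The contrast of the sorted fractions in vehicle-exposed mice shows which cells the sort parted without added odor. Neutrophil transcripts were among those far higher in the arrays titled GFP+. Fn1, which encodes fibronectin, had the largest fitted log2 difference (9.08 ± 0.27, SE, n = 4 pools), and the neutrophil granule and alarmin genes Retnlg (491-fold, 8.94 ± 0.16), Mmp8 (487-fold, 8.93 ± 0.18), Mmp9 (8.79 ± 0.28), S100a8 (444-fold, 8.79 ± 0.29) and S100a9 (441-fold, 8.78 ± 0.17) followed. The surface antigen genes Ly6c1 and Ly6c2, the plasma haptoglobin gene Hp and the macrophage chitinase-like gene Chil3 completed the 10 largest. Fn1, Mmp9 and Hp lay at or below the negative control median of every vehicle array titled GFP-, so they were at least 114-, 198- and 222-fold higher against that median, while Ly6c1, Ly6c2 and Chil3 were 466-, 422- and 388-fold higher. On the other side, the 10 largest differences were all odorant receptors, led by Olfr309, 69.6-fold lower in arrays titled GFP+ (-6.12 ± 0.23), Olfr536 (67.4-fold, -6.08 ± 0.21), Olfr372 (46.5-fold) and Olfr110 (44.6-fold), and ending with Olfr281 (24.9-fold, -4.64 ± 0.16). Olfr533, Olfr1093, Olfr613, Olfr494 and Olfr481 lay between, with Olfr1093 and Olfr613 at or below the control median in the arrays titled GFP+ (at least 22.6- and 17.3-fold lower). In all, 5064 of 19505 genes passed an adjusted p of 0.05, 2406 higher and 2658 lower, and 1608 and 541 of them by 2-fold or more. This balance depended on the scaling of the arrays: the higher and lower calls were 1818 and 12539 after median centring, 1512 and 15293 after centring on housekeeping genes, 2792 and 1411 after cyclic loess, and 4154 and 699 after centring on mature neuron genes. The median difference of all genes moved from -0.14 to -0.51, -0.71, -0.02 and 0.17 with those 4 scalings. Housekeeping centring is not neutral between the fractions, since camera called those genes themselves higher in the arrays titled GFP+. It lowered every gene alike, S100a5 for instance from -1.23 to -1.80, by more than the housekeeping median of 0.08.

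Gene lists fixed beforehand placed these genes by cell type in the vehicle pools. All 11 measured neutrophil genes were higher in the arrays titled GFP+ (median log2 difference 8.37; camera adjusted p = 8.8e-25; adjusted p = 0.0459 with an estimated correlation). So were all 11 genes of microvillar and brush cells (median 2.49; 4.7e-13; adjusted p = 0.0459 with an estimated correlation), among them the channel gene Trpm5 (3.75 ± 0.30) and the ionocyte regulator Foxi1 (4.03 ± 0.24). All 15 macrophage and antigen presentation genes were higher, for instance lysozyme Lyz2 (7.30 ± 0.21) and the Fc receptor subunit Fcer1g (6.75 ± 0.19), with a median of 3.96 (9.1e-20; adjusted p = 0.0606 with an estimated correlation). Of 10 olfactory progenitor genes, 8 were higher over all genes and 9 adjusted over the list alone, including the proliferation marker Mki67 (at least 35.2-fold) and the stem cell factor receptor Kit (at least 11.5-fold), with a median of 1.40, or 0.92 with dim members at their bound (3e-08; adjusted p = 0.0606 with an estimated correlation). Of 21 immediate early genes, 16 were higher (17 adjusted over the list alone), with Egr1 at 5.94 ± 0.19, Egr2 at 5.81 ± 0.23 and Fos at 5.27 ± 0.14 (median 1.86; 7.9e-15; adjusted p = 0.0606 with an estimated correlation). Of 12 sustentacular genes, 7 were higher and 1 lower, the same counts as adjusted over the list alone; the sulfotransferase Sult1c1 stood at 2.85 ± 0.22 and Cyp1a2 at 2.18 ± 0.26 (list adjusted p = 0.00017; adjusted p = 0.169 with an estimated correlation). B and T lymphocyte genes, 8 of 10 at or below the control median in 1 of the fractions, gave 6 higher (8 adjusted over the list alone; 0.00016; adjusted p = 0.199 with an estimated correlation). The immature neuron list was mixed, with 6 of 15 higher and 2 lower (7 and 3 adjusted over the list alone; 0.0006; adjusted p = 0.197 with an estimated correlation). Its members Gng8, a G protein subunit, and Nhlh1, a neuronal transcription factor, stood at 4.27 ± 0.16 and at least 9.61-fold higher, and its median of 0.12 turned negative with median or housekeeping centring.

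Transcripts of mature neurons in the same vehicle pools were lower in the arrays titled GFP+. Of 18 mature olfactory sensory neuron genes, 11 were lower (13 adjusted over the list alone) and 0 higher, among them the phosphodiesterase Pde1c (-0.81 ± 0.09), the chloride channel Ano2 (-0.48 ± 0.06) and the exchanger Slc24a4 (-0.46 ± 0.09), with a list median of -0.32 (camera adjusted p = 0.00021; adjusted p = 0.199 with an estimated correlation). That median became -0.69 after median centring, -0.89 after housekeeping centring and -0.24 after cyclic loess. Of 13 measured genes linked to activity in these neurons, 7 were lower and 1 higher (7 and 2 adjusted over the list alone; median -0.56; 0.0052; adjusted p = 0.0785 with an estimated correlation). Pcp4l1, a relative of a calmodulin-binding protein, was 4.27-fold lower (-2.10 ± 0.10), and the membrane proteins Lrrc3b (-1.69 ± 0.11) and Kirrel2 (-1.10 ± 0.14), the latter an adhesion molecule of sensory axons, were lower as well. Of 17 axon guidance and adhesion genes, 9 were lower, also when adjusted over the list alone, with Epha5 at -0.86 ± 0.15 and Plxna3 at -0.74 ± 0.16 (median -0.29; 0.018; adjusted p = 0.199 with an estimated correlation). Of 10 genes of ciliated respiratory cells 4 were lower, including Ccdc113 (-1.12 ± 0.20; list adjusted p = 0.041; adjusted p = 0.181 with an estimated correlation). With arrays centred on the mature neuron genes, the axon guidance median became 0.02 and Plxna3 was no longer past the threshold (adjusted p = 0.0729). Slc24a4, itself 1 of the genes used for that centring, also lost its call (-0.15, adjusted p = 0.209).

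**Figure D2:**
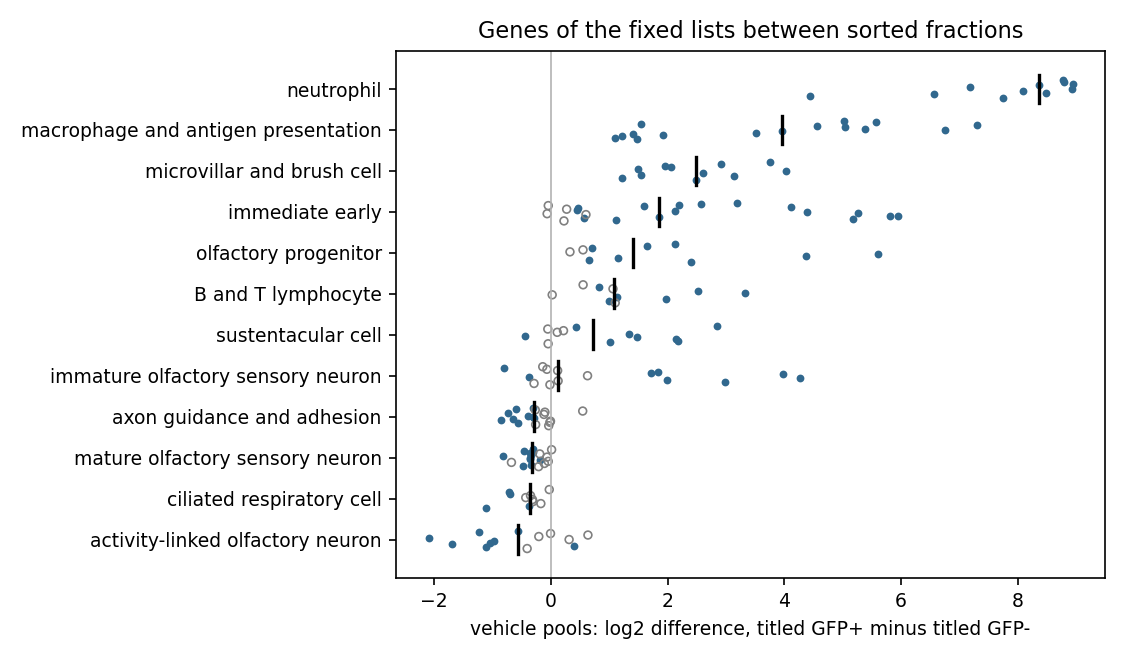
Log2 difference (array titled GFP+ minus array titled GFP-) of the members of fixed gene lists in the vehicle pools, with list medians. The cell type field of the labels reverses the sign. Neutrophil genes lie highest, with a median of 8.37 in the vehicle pools, and the axon guidance median turns from -0.29 to 0.02 when arrays are centred on mature neuron genes, while the immature neuron median turns negative with median or housekeeping centring.

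Odorant and trace amine-associated receptors, of which a sensory neuron expresses a single gene, were spread over both sides of the sort in the vehicle pools. Of the 1105 receptors, 263 were higher and 525 lower in arrays titled GFP+ (285 and 568 adjusted over the list alone), and the median was -0.59. The median became -0.95 after median centring, -1.15 after housekeeping centring, with 214 higher and 704 lower, and -0.28 after centring on mature neuron genes, with 309 and 455. Olfr1507 (352-fold, 8.46 ± 0.29), Olfr99 (321-fold, 8.33 ± 0.33), Olfr1297 (308-fold, 8.27 ± 0.27) and Olfr1213 (264-fold, 8.04 ± 0.40) had the largest positive differences among receptors, against -6.12 ± 0.23 for Olfr309. The 15 trace amine-associated receptors parted as well, with 3 higher and 7 lower (4 and 7 adjusted over the list alone). Taar2 was higher (2.32 ± 0.41), and Taar4 (-3.09 ± 0.21) and Taar9 (-2.96 ± 0.35) were lower. As lists, the odorant receptors had an adjusted p of 0.0033 (adjusted p = 0.419 with an estimated correlation) and the trace amine-associated receptors one of 0.076. The odor pools, which share no mice with the vehicle pools, gave nearly the same order of receptors: across the 1105 receptors, which are not independent replicates, Pearson's r between the differences of the 2 treatments was 0.980 and Spearman's rho 0.969. Of 729 receptors past the threshold in both treatments, 728 had the same direction, 231 higher and 497 lower in the arrays titled GFP+, where independent lists would share 60.5 and 255.6. A difference of 8-fold or more was found in both treatments for 110 receptors on the higher side and 69 on the lower side.

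**Figure D3:**
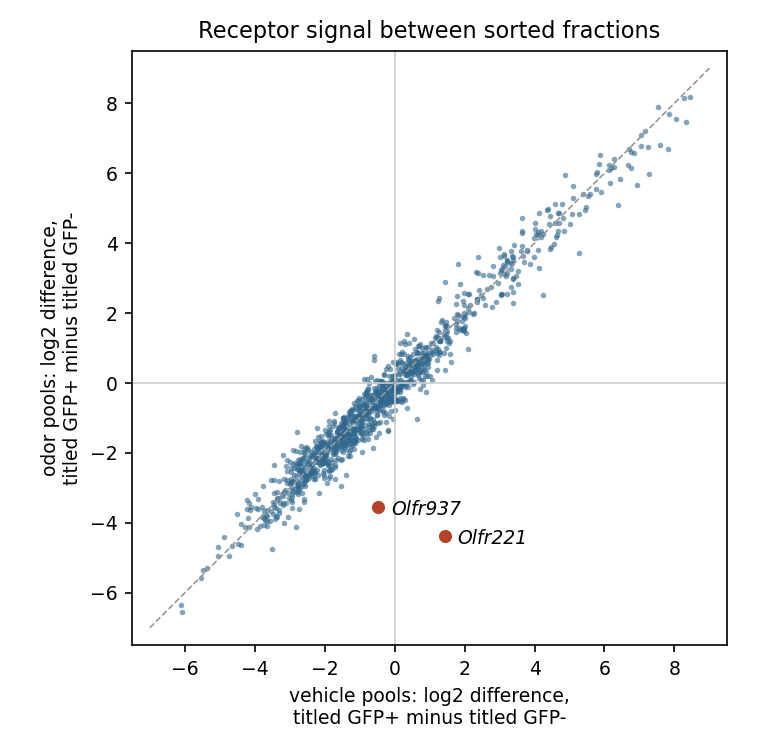
Log2 difference (titled GFP+ minus titled GFP-) of each of the 1105 receptors in the vehicle pools (x axis) and in the odor pools (y axis), each the mean of 4 pools; the cell type field of the labels reverses both signs. Receptors lie along the diagonal (r = 0.980 across receptors), and Olfr221 and Olfr937 fall below it.

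The same contrast in mice exposed to whiskey lactone asks which cells were parted by the sort after odor. Mmp9, a gelatinase of neutrophils, was at least 272-fold higher in the arrays titled GFP+ (fitted log2 difference 9.10 ± 0.28, SE, n = 4 pools), Ly6c2 544-fold, Retnlg 535-fold (9.06 ± 0.16) and Fn1 at least 130-fold. Mmp8, S100a9, Hp, Ly6c1, S100a8 and the neutrophil granule gene Ngp (330-fold, 8.37 ± 0.23) completed the 10 largest. Lower in the arrays titled GFP+ were again odorant receptors, Olfr536 by 94.2-fold (-6.56 ± 0.21), Olfr309 by 81.6-fold (-6.35 ± 0.23), Olfr372 by 48.0-fold and Olfr110 by 40.7-fold, then Olfr533, Olfr481 (at least 17.9-fold), Olfr613 (at least 16.1-fold), Olfr1448 (26.6-fold, -4.73 ± 0.23), Olfr1093 and Olfr281 (25.4-fold). On the higher side, the receptors with the largest differences were Olfr1507 (8.18 ± 0.29), Olfr1297 (8.16 ± 0.27), Olfr393 (7.90 ± 0.25) and Olfr1406 (207-fold). In total 5362 genes passed the threshold, 2502 higher and 2860 lower, and 254 and 538 of them were receptors (276 and 582 adjusted over the list alone, median -0.64). The receptor median became -1.02 and -1.28 after median and housekeeping centring, the latter with 205 higher and 734 lower, and -0.37 after centring on mature neuron genes. The higher and lower calls were 1902 and 12906 after median centring, 1561 and 15809 after housekeeping centring, 2922 and 1395 after cyclic loess, and 3735 and 831 after centring on mature neuron genes, and the median of all genes moved from -0.15 to -0.53, -0.79, -0.02 and 0.12.

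Cell type lists in the odor pools followed. All 11 neutrophil genes and all 11 microvillar genes were higher in the arrays titled GFP+ (adjusted p = 0.044 with an estimated correlation for each list), Trpm5 at 3.90 ± 0.30. Higher too were 14 of 15 macrophage genes (15 adjusted over the list alone), 8 of 10 progenitor genes (9 adjusted over the list alone), with Mki67 at least 72.4-fold higher, and 17 of 21 immediate early genes, also when adjusted over the list alone, with Egr2 at 6.42 ± 0.23 and the antiproliferative gene Btg2 at 5.70 ± 0.20. The adjusted p of each of these 3 lists was 0.061 with an estimated correlation. Mature neuron genes were lower for 10 of 18 (12 adjusted over the list alone) and higher for 0, with Pde1c at -0.80 ± 0.09 (camera adjusted p = 0.00037; adjusted p = 0.227 with an estimated correlation). In the activity-linked list 7 of 13 were lower and 1 higher, the same counts as adjusted over the list alone (0.0071; adjusted p = 0.0825 with an estimated correlation), among them Pcp4l1 (-1.89 ± 0.10), Lrrc3b (-1.64 ± 0.11) and the protocadherin Pcdh10 (-1.26 ± 0.15). Of the 15 trace amine-associated receptors 2 were higher and 8 lower (4 and 8 adjusted over the list alone; list adjusted p = 0.101), Taar2 at 3.19 ± 0.41 and Taar4 at -2.87 ± 0.21.

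The readout of the assay is the difference of the fraction contrasts between treatments, which shows receptors whose place in the sort differed after whiskey lactone. Olfr221 changed sides. In the vehicle pools Olfr221 was 2.69-fold higher in the arrays titled GFP+ (1.43 ± 0.40, SE; adjusted p = 0.0180; higher in 4 of 4 pools), and in the odor pools it was 20.8-fold lower there (-4.38 ± 0.40, adjusted p = 2.19e-06; lower in 4 of 4 pools). The difference between treatments was -5.81 ± 0.56 (adjusted p = 0.00306 over all genes and 0.000173 adjusted over the receptor list alone). Olfr937 followed, with -0.46 ± 0.32 in the vehicle pools (adjusted p = 0.311; lower in 2 of 4 pools; -0.83 and -1.03 after median and housekeeping centring, adjusted p = 0.0360 and 0.0110) and an 11.6-fold lower level in the odor arrays titled GFP+ (-3.54 ± 0.32, adjusted p = 2.45e-06; lower in 4 of 4 pools). Its difference between treatments, -3.07 ± 0.46, passed adjusted over the receptor list alone (0.00934) and not over all genes (0.165). By the cell type field of the labels, both differences shifted toward the fraction called GFP+ after odor. Of 19505 genes, 1 passed the threshold and 638 had an unadjusted p under 0.05; of 1105 receptors, 2 passed adjusted over the list alone, and 84 had an unadjusted p under 0.05. The call of Olfr221 over all genes was lost with the replicate number as a block (adjusted p = 0.164), with all features tested (0.102), without the variance trend (0.0572) and with robust estimation (0.208), and over all alternatives its adjusted p ranged from 2.81e-05 to 0.208. Its vehicle difference lost its call with all features (0.0546), with robust estimation (0.0507), and without vehicle pool 1, 2 or 3 (0.0630, 0.0891 and 0.0653).

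**Figure D4:**
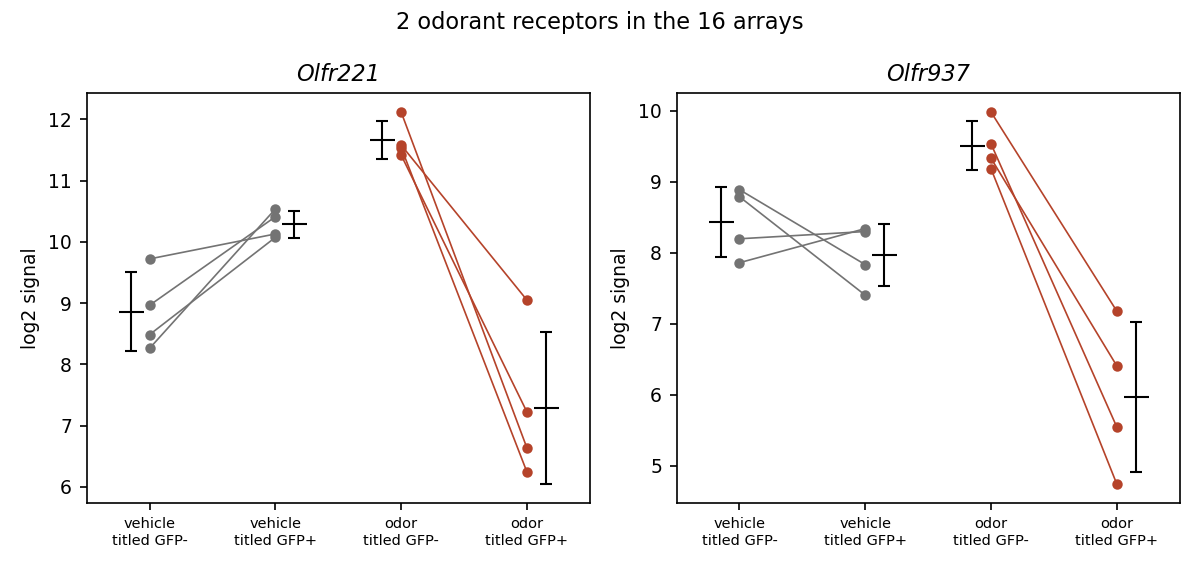
Log2 signal of Olfr221 and Olfr937 in each array (points), with group means and SD (n = 4 pools per group) and lines joining the 2 fractions of a pool; fractions are named by array title, which the cell type field reverses. Olfr221 is higher in the array titled GFP+ in all 4 vehicle pools and lower there in all 4 odor pools.

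Other receptors did not pass in the contrast between treatments without pairing by number. Olfr905 was next in order of p, at -1.29 ± 0.27 (adjusted p = 0.130 over the list alone), before Olfr597 (0.98 ± 0.24), Olfr1241 (-1.73 ± 0.43), Olfr769 (1.46 ± 0.37), Olfr691 (1.40 ± 0.36), Olfr229 (-1.42 ± 0.37), Olfr772 (1.35 ± 0.35) and Olfr773 (1.25 ± 0.33), each with an adjusted p of 0.234 over the list alone. Olfr905 and Olfr229 lay at or below the negative control median in all odor arrays titled GFP+, so their values are not exact sizes. S100a5 (-0.11 ± 0.13) and Omp (-0.08 ± 0.07) did not differ between treatments in their fraction contrast (adjusted p = 0.999 each). Of 21 immediate early genes 0 passed, also when adjusted over the list alone. Nr4a2, a nuclear receptor, stood at 1.46 ± 0.44 and the transcription factor Egr3 at 0.77 ± 0.30. The list median was 0.52 (camera adjusted p = 0.0036; adjusted p = 0.962 with an estimated correlation). Red cell genes stood higher in the same contrast, Alas2 at 0.94 ± 0.29 and Slc4a1 at 1.25 ± 0.51 (adjusted p = 0.999 each over all genes). With the replicate number as a block, 4 receptors passed adjusted over the list alone, namely Olfr221 (0.00927), Olfr937 (0.0108), Olfr773 (0.0247) and Olfr772 (0.0343), and 0 of 19505 genes passed over all genes with limma. The number of receptors past the list threshold rose from 2 to 4 without odor pool 1 and without odor pool 4.

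Comparing odor with vehicle within the arrays titled GFP+ shows in which fraction the level itself differed. Olfr221 was 8.0-fold lower after whiskey lactone, at 7.29 ± 1.24 in odor and 10.29 ± 0.22 in vehicle arrays (SD, n = 4 each; log2 difference -3.0 ± 0.44, SE; adjusted p = 0.0412). It was the only gene of 19505 past the threshold, with 951 at an unadjusted p under 0.05. Adjusted over the receptor list alone, Olfr937 (4.0-fold lower, -2.0 ± 0.39, 0.0288), Olfr1448 (-1.23 ± 0.25, 0.0288) and Olfr905 (at least 1.61-fold, 0.0288) were lower as well, and Olfr1034 was higher (1.37 ± 0.28, 0.0302). Of the activity-linked list, 0 of 13 passed over all genes and 3 adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.229 with an estimated correlation): Pcdh10 (1.32 ± 0.29), Kirrel2 (1.01 ± 0.24) and Lrrc3b (0.90 ± 0.21), each at 0.00196. Immediate early genes had 0 of 21 past the threshold, also when adjusted over the list alone, with a median of 0.59 (7.4e-06; adjusted p = 0.965 with an estimated correlation). Their members Fosb (1.53 ± 0.72) and Nr4a1 (1.42 ± 0.57) had wide errors. Red cell genes lay higher in the same arrays without passing over all genes. Alas2 stood at 1.07 ± 0.38, Slc4a1 at 1.16 ± 0.40 and Car1 at 1.03 ± 0.64. Rhag (1.35 ± 0.50) and Epb42 (1.38 ± 0.33) are not members of the fixed erythroid list. Etv5, an ETS transcription factor, stood at 1.05 ± 0.20 (adjusted p = 0.275), S100a5 at -0.04 ± 0.14 and Omp at -0.06 ± 0.06. The call of Olfr221 was lost when any pool other than odor pool 4 was left out (adjusted p = 0.0751 to 0.432). Without odor pool 4 the count was 8 genes and 13 receptors, and receptors fell to 1 without odor pool 1, odor pool 2 or vehicle pool 1 and to 2 without odor pool 3 or vehicle pool 4. The call was also lost without a block, with the replicate number as a block, without dim genes, with all features, without the variance trend, with robust estimation and with array weights (0.0615 to 0.513).

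Within the arrays titled GFP-, which the cell type field calls GFP+, 3 of 1105 receptors were higher after odor and 1 lower, adjusted over the list alone. Olfr221 had log2 signals of 11.66 ± 0.31 in odor and 8.86 ± 0.65 in vehicle arrays (SD, n = 4 each), a 6.99-fold difference (2.80 ± 0.44, SE) with an adjusted p of 0.0996 over all genes and 0.00564 adjusted over the receptor list alone. It passed over all genes without a block (0.00419), with housekeeping centring (0.0478), with array weights (0.0322), without odor pool 4 (0.00178) and without the pools numbered 4 (0.000349). Over all alternatives its adjusted p ranged from 0.000349 to 0.341. On the same list Olfr1022 (5.63-fold, 2.49 ± 0.42, 0.00691) and Olfr1221 (4.67-fold, 2.22 ± 0.40, 0.0112) were higher and Olfr971 was lower (3.39-fold, -1.76 ± 0.37, 0.0392). In the arrays titled GFP+ Olfr1022 had log2 signals of 5.63 to 7.79 in odor and 4.43 to 6.05 in vehicle arrays. Olfr1221 had 6.84 to 7.76 and 6.08 to 7.45 there. Neither Olfr1022 nor Olfr1221 passed in the contrast between treatments, so their higher level is not shown to be particular to 1 fraction. Olfr937, at 1.07 ± 0.39, did not pass without pairing (0.448). Of 19505 genes 0 passed with limma, with 1147 at an unadjusted p under 0.05; among negative differences the smallest p belonged to Mpp4, a scaffold protein gene (adjusted p = 0.157, not above the negative control median in any of these arrays, so no size is given), Ypel3 (-0.44 ± 0.09, 0.255) and Olfr971. S100a5 was at 0.07 ± 0.14 and Omp at 0.02 ± 0.06. In the activity-linked list 4 genes were higher and 1 lower adjusted over the list alone, namely Pcdh10 (1.55 ± 0.29), Lrrc3b (0.85 ± 0.21), Kirrel2 (0.83 ± 0.24) and the semaphorin Sema7a (0.50 ± 0.10), and Pcdh17 (-0.53 ± 0.20), with 0 past over all genes (camera adjusted p = 0.039; adjusted p = 0.189 with an estimated correlation). Of 9 fibroblast genes 0 passed, also when adjusted over the list alone. Camera called the list lower (0.039; adjusted p = 0.189 with an estimated correlation), but 7 of the 9 lay at or below the negative control median in both groups.

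Odor and vehicle pools of the same replicate number deviated together in this fraction, so paired values stand beside the unpaired ones. With the replicate number as a block, 15 genes passed the threshold in the arrays titled GFP-, all higher after odor. They were led by Olfr221 (2.80 ± 0.25, SE; adjusted p = 0.00190), Pcdh10 (1.55 ± 0.15, 0.00201), Etv5 (0.93 ± 0.09, 0.00201), the potassium channel subunit Kcng1 (1.5 ± 0.15, 0.00201) and Kirrel2 (0.83 ± 0.08, 0.00201), and included Olfr1221 (2.22 ± 0.26, 0.00694), Olfr1022 (0.0236) and Lrrc3b (0.85 ± 0.12, 0.0236). Of the receptors, 75 passed adjusted over the list alone, 48 higher and 27 lower, and Olfr937 was among those higher (1.07 ± 0.19, 0.0113). The paired list tests called activity-linked genes (adjusted p = 0.0021; adjusted p = 0.476 with an estimated correlation) and immediate early genes (0.0049; adjusted p = 0.631 with an estimated correlation) as higher. They called Nrf2 and phase II enzymes (0.0255; adjusted p = 0.476 with an estimated correlation) as lower. The fibroblast list was called lower too (0.0238; adjusted p = 0.476 with an estimated correlation), with the same 7 of 9 genes at background.

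The same pairing was applied to the arrays titled GFP+. With the replicate number as a block, 2 genes passed there, Kirrel2 (1.01 ± 0.11, SE; adjusted p = 0.0357) and Etv5 (1.05 ± 0.12, 0.0357), both higher after odor, and Olfr221 did not (0.0954). Adjusted over the receptor list alone 8 receptors passed, 3 higher and 5 lower, with Olfr221 at 0.0137, Olfr937 at 0.0253 and Olfr1034 at 0.0354, while Olfr1448 and Olfr905 did not pass (0.0614 each). An exchange of treatment labels within the replicate numbers called up to 154 genes and 30 receptors in these arrays, against the real 2 and 8. The paired calls of genes and receptors here thus do not stand out from exchanged labels. The paired list tests called 6 lists. Camera called the immediate early list higher (adjusted p = 7.2e-10, but 0.671 with an estimated correlation). Of its genes, 9 of 21 were higher adjusted over the list alone and 0 over all genes. The activity-linked list was also called higher (0.0010, but 0.671 with an estimated correlation), with 3 of 13 higher adjusted over the list alone and 1 over all genes. Camera called the sustentacular list lower (0.0010, but 0.671 with an estimated correlation), with 1 of 12 genes lower adjusted over the list alone. The macrophage list was also called lower (0.0010, but 0.739 with an estimated correlation), with 3 of 15 lower adjusted that way. In both lists 0 genes passed over all genes. Bowman's gland (0.0287) and fibroblast genes (0.0496) were called lower too, but 2 of 11 and 5 of 9 of them lay at or below the negative control median in both groups and 2 more of each in 1 group. Both medians were 0 with such genes at their bound. None of the 6 was called with an estimated correlation (adjusted p = 0.671 to 0.739 with an estimated correlation).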

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

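The tests of the array titles, of a shift of all receptors, of cross-hybridization and of neurons that pass between fractions were chosen after the results were seen; the counts over other splits of the samples were planned. In all 8 pools S100a5 was lower in the array titled GFP+, the reverse of what the reporter's name implies. Loss of the transcript from the reporter allele with correct titles would leave non-neuronal genes at or below 0 in the arrays titled GFP+, and the median difference of 49 neutrophil, macrophage, sustentacular and microvillar genes was 2.85 ± 0.306 (SD of 8 pools), above 0 in each pool. An exchange of arrays in single pools would leave pools of opposite sign, and 0 were found. Titles that name the fractions the wrong way round, with the cell type field correct, may account for the pattern in all 8 pools. The labels hold both namings, and no biological explanation other than that loss was tested.

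Olfr221 and Olfr937 differed between treatments in their fraction contrast by -5.81 and -3.07, tested as an interaction. A shift of all receptors through normalization or neuron content is argued against by the other 1103 receptors, whose median was -0.0382 and whose largest value in size was 1.73. Signal of one receptor arising wholly from the other is argued against by the vehicle pools, where their fraction differences lay 1.89 ± 0.874 apart (SD, n = 4 pools). Unequal differences cannot exclude a partial share of signal from the other receptor. This share and hybridization from an unlisted transcript stay open because no probe sequences were at hand. Passage of neurons expressing these receptors from the fraction titled GFP+ to the one titled GFP- after whiskey lactone may account for both. The level in arrays titled GFP- was higher by 2.80 ± 0.44 for Olfr221 and 1.07 ± 0.39 for Olfr937 while it was lower in arrays titled GFP+ (-3.0 and -2.0). These values are the parts of the difference between treatments that singled out the receptors, so they are not a separate test of passage. For Olfr937 the higher level in arrays titled GFP- did not pass over all genes without pairing (limma, adjusted p = 0.769).

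Counts over other splits of the same samples were set beside each result. For the fraction contrast, 1 of 35 splits of the arrays gave as many genes in the vehicle pools (5064, highest other 0) and 1 of 35 in the odor pools (5362, highest other 1940). Only 8 of the 35 exchange fractions within all pools, too few for a share under 0.05, and among these the highest other was 0 in both treatments. The rest keep both fractions of at least 1 pool together, and 3 of them left no estimate. For the difference between treatments, 5 of 35 splits of the pools gave at least the real count of 1 gene (highest other 65), and 5 of 35 the real 2 receptors (highest other 109), so over all 35 chance cannot be excluded. Only 8 of these splits keep the 4 numbers in each group, too few for a share under 0.05, and among them the highest other was 0 genes and 1 receptor. Within the arrays titled GFP+ 7 of 35 splits gave at least the real 1 gene (highest other 400), and within those titled GFP- 35 of 35 gave at least the real 0 (highest other 11). Every split reaches a count of 0, so the latter share was fixed in advance and says nothing about chance. The split with 65, 109, 400 and 11 calls set the pools numbered 1 and 3 of both treatments against those numbered 2 and 4, which points to a structure of the pools by number. With the replicate number as a block, the counts were 0 genes and 4 receptors between treatments, 2 genes in arrays titled GFP+ and 15 genes in arrays titled GFP-. With that block the 8 exchanges of treatment within numbers are again too few for a share under 0.05. The real one and the highest other gave 15 and 1 genes, and 75 and 20 receptors, in arrays titled GFP-, 2 and 154 genes, and 8 and 30 receptors, in arrays titled GFP+, and 4 and 0 receptors between treatments.

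Of 195 groups of 4 values tested for a value far from the rest (Dixon's criterion), 13 held one, 6.67%, and chance gives about 1 in 20. In fraction differences, Kirrel2 was -1.75 in vehicle pool 1 against -0.93 to -0.86 in the others. In odor pool 4, S100a9 was 8.17 against 8.85 to 8.94, Hp 7.10 against 9.06 to 9.43, and Alas2 1.73 against 2.68 to 2.80. Pcp4l1 was -1.57 in odor pool 2 against -2.03 to -1.98. In log2 signals of the arrays titled GFP+, Pcdh10 was 9.57 in odor pool 2 against 8.89 to 8.97, and Slc4a1 was 10.22 in vehicle pool 2 against 11.70 to 11.93. In the arrays titled GFP-, S100a5 was 16.23 in vehicle pool 4 against 16.59 to 16.62, and Olfr1221 was 7.42 in odor pool 1 against 8.40 to 8.52. Mpp4 was 3.63 in odor pool 1 against 4.03 to 4.07 and 5.03 in vehicle pool 3 against 4.79 to 4.81, all below the negative control medians of their arrays. Kirrel2 was 16.18 in odor pool 3 against 15.39 to 15.50, and 15.13 in vehicle pool 3 against 14.65 to 14.70.

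Transcript features outside the genes tested also differed between fractions. They were features without a gene name, counted together with the 67 further features of named genes. With all features tested, 371 of 2701 (13.7%) passed in the vehicle pools against 2.99% of the 5222 negative control features, and 396 (14.7%) against 3.45% in the odor pools.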

How the results depend on the processing

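Centring on mature neuron genes, leaving out the pools numbered 4 and the paired list tests were chosen after the data were seen; the other alternatives were planned. Of 149 named results for genes, 124 kept their direction and their side of the threshold under all alternatives. Of the single values, 3079 were the same, 25 lost and 30 gained a call, and 8 changed sign. Genes past the threshold between fractions numbered 14357 (vehicle) and 14808 (odor) after median centring and 16805 and 17370 after housekeeping centring, against 5064 and 5362; 4479, 4767, 4198 and 4481 of them were among the original calls. Leaving out pools gave 3552 to 5143 and 3709 to 5518. Housekeeping centring is not neutral here, because those genes lay higher themselves in arrays titled GFP+. For the difference between treatments the count fell from 1 to 0 with the replicate block by number, with all features, without the variance trend and with robust estimation. Its receptor count of 2 became 4 with the replicate block, 1 with all features and 2 to 4 with pools left out. In arrays titled GFP+, the count of 1 gene after odor became 0 without a block, without dim genes, with all features, without the trend, with robust estimation and with array weights, 2 with the replicate block (Kirrel2 and Etv5, both higher), 2 without the pools numbered 4, and 0 to 8 with pools left out. Its 5 receptors became 3 without a block, 8 with the replicate block, 1 with all features, 1 with array weights, 10 without the pools numbered 4, and 1 to 13 with pools left out. Fraction differences of same-numbered pools correlated at 0.253, 0.209, 0.128 and 0.073. In arrays titled GFP-, the count of 0 genes became 15 with the replicate block, 1 without a block, 1 after housekeeping centring, 2 with array weights, 2 without the pools numbered 4, and 0 to 2 with pools left out. Its 4 receptors became 75 with the replicate block, 2 without a block, 8 with array weights, 7 after mature neuron centring, and 2 to 6 with pools left out. Lists called by camera fell from 19 to 2 in each fraction contrast with an estimated correlation, and from 1, 2 and 2 to 0, 0 and 0 in the other 3 comparisons, with fry 0, 0 and 0 too; the paired test called 6 lists in arrays titled GFP+, 4 in arrays titled GFP- and 1 for the difference between treatments. Omp turned to 0.25 (vehicle) and 0.14 (odor) between fractions after mature neuron centring, which uses Omp itself. It turned to -0.0147 after median centring in odor against vehicle in arrays titled GFP-. With pools left out, S100a5 ranged from -0.19 to 0.0034 for the difference between treatments, from -0.17 to 0.0820 in arrays titled GFP+ and from -0.0225 to 0.124 in arrays titled GFP-, where Omp ranged from -0.0320 to 0.0459; none of these passed a threshold. Beyond the calls given in the report, the replicate block changed no call of a named gene over all genes. The cause was not tested. Array signals near the negative control medians of 4.98 to 5.59 limit what can be seen of dim genes, and 81.0 to 87.0% of receptors lay above that median.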

Other observations

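Tests of neighbouring receptors and of the immediate early genes were written before their results were seen; the test of an odor effect in both fractions was chosen afterwards. Cell types and pathways that the report leaves out also differed between the fractions in the vehicle pools, with signs that follow the titles and that the cell type field reverses. All 3 measured erythroid genes were higher in arrays titled GFP+, also when adjusted over the list alone, with the carbonic anhydrase Car1 at least 18.0-fold higher. Of 319 vomeronasal receptors, 31 were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 0.015; adjusted p = 0.199 with an estimated correlation), but 293 of them lay at or below the negative control median in both fractions, so no median is given. Nrf2 and phase II enzymes, such as Mgst1 (4.27 ± 0.27), had 6 of 15 higher and 2 lower (6 and 3 adjusted over the list alone; 0.02; adjusted p = 0.197 with an estimated correlation). Heat shock genes, such as Hspa1a (1.91 ± 0.14), had 4 of 9 higher and 1 lower (0.0024, adjusted p = 0.197 with an estimated correlation). Vomeronasal and GC-D neuron genes had 3 of 7 higher and 1 lower (0.0012, adjusted p = 0.0785 with an estimated correlation). Bowman's gland genes had 3 of 11 higher (0.034, adjusted p = 0.349 with an estimated correlation) and housekeeping genes 4 of 10 higher and 1 lower (0.022, adjusted p = 0.181 with an estimated correlation). In these 4 lists the counts were the same adjusted over the list alone. The medians of these lists and of the Nrf2 list turned negative with median or housekeeping centring. For the housekeeping list its own centring shows nothing, because its median of 0.08 lay below the list mean that was subtracted. Interferon response genes (2 of 12 higher, 2 lower), receptor choice genes (2 of 17 higher, 4 lower), horizontal basal cell (1 of 10 higher), ensheathing glia (1 of 8), fibroblast (2 of 9) and endothelial genes (0 of 8) were not called as lists (adjusted p = 0.33 to 0.66). Of the last 4 lists 9, 5, 5 and 5 members lay at or below the negative control median in both fractions.

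Odor against vehicle moved further list members when adjusted over the list alone, none of them past the threshold over all genes. In arrays titled GFP+, the heme synthesis gene Alas2 (1.07 ± 0.38) and the anion exchanger gene Slc4a1 of red cells (1.16 ± 0.40) were higher after odor (0.0175 each), and Stmn4, a stathmin of immature neurons, was lower (-0.47 ± 0.12, 0.0184), though not with the replicate number as a block (0.0569). Alas2 and Slc4a1 also differed in the contrast between treatments (0.94 ± 0.29 and 1.25 ± 0.51, at 0.0193 and 0.0433), Slc4a1 not with that block (0.0747). In arrays titled GFP-, the gland gene Bpifb9a (1.75 ± 0.66, 0.0493) was higher. The gland genes Obp1a and Muc5b passed as well (0.0493 and 0.00748), without a size because of signals at or below the negative control median, and Lcn4 was at least 1.05-fold lower (0.0493). The heat shock genes Hspa1a (-1.08 ± 0.28, 0.00967) and Hspa1b (-0.96 ± 0.29, 0.0155) were lower.

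The odor effect was also tested as an average over both fractions. Averaged over the fractions with the replicate number as a block, 11 genes passed the threshold, 10 of them higher, among them Etv5 (0.99 ± 0.08, adjusted p = 0.000434), Kirrel2 (0.92 ± 0.07, 0.000434), Pcdh10 (1.44 ± 0.15, 0.00358), Kcng1 (1.13 ± 0.13, 0.00575) and Lrrc3b (0.87 ± 0.11, 0.0185). Olfr971 was lower (0.00391), with all odor arrays titled GFP+ at or below the negative control median, so no size is given. In arrays titled GFP+ alone only Kirrel2 and Etv5 passed with that block, and without it 0 of the 10 higher genes passed in either fraction. The other 7 exchanges of treatment within numbers gave 0 genes, too few exchanges for a share under 0.05, and without the block 0 genes passed. An odor effect common to both sides of the sort is a hypothesis, and these 11 genes do not establish it for each fraction.

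Receptors that neighbour each other in the genome had closer fraction differences than receptors in shuffled order. Over 1088 adjacent pairs the mean absolute difference of their log2 fraction differences was 2.21, against 2.46 for shuffled orders (2.26 to 2.62), with a one-sided permutation p of 1e-04, the smallest that 10000 shuffles can give. Shared regulation, a shared zone of the epithelium or sequence likeness between neighbours may each account for this value of 2.21; none of these was tested apart.

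Immediate early genes were higher in the arrays titled GFP+, and their mean over the 8 arrays titled GFP+ was set against 2 other lists. With the neutrophil list Pearson's r was 0.633 (exact permutation p = 0.0913, adjusted p = 0.183; rho = 0.595, exact p = 0.132; r = 0.717 without the 2 farthest arrays, n = 8). With the heat shock list r was 0.437 (exact permutation p = 0.276, adjusted p = 0.276; rho = 0.571, exact p = 0.151; r = 0.614 without the 2 farthest arrays, n = 8). RNA of neutrophils and a response to dissociation cannot be told apart as sources of these transcripts with 8 arrays, and neither is excluded. The 8 arrays join odor and vehicle pools, which these correlations do not separate. Other cell types whose genes were higher in these arrays were not tested as sources.

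The Y-linked gene Eif2s3y had log2 signals of 2.49 to 2.80 in the 4 arrays of the pools numbered 4 and of 10.06 to 11.43 in the other arrays, with odor and vehicle alike.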
